A study of Homo sapiens with 5 samples.

How the data were processed

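Chromatin immunoprecipitation with sequencing (ChIP-seq) was performed on VCaP cells, an established human prostate cancer line. Antibodies against 2 histone marks were used, acetylation of histone H3 at lysine 27 (H3K27ac) and monomethylation at lysine 4 (H3K4me1). The labels give 2 libraries per mark and 1 input library, which is chromatin sequenced without immunoprecipitation. The input library is not analysed here as a sample of its own. Replicates were taken from the numbers in the labels. No label states whether the replicates came from separate cultures, so the spread between them may be technical. P-values of the comparison of marks by library measure only the spread between these samples. P-values from randomly placed regions or shuffled windows include no spread between samples.

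Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sheared by focused sonication, and libraries were amplified and size selected on beads before sequencing. The submitters' processing notes name bcl2fastq 2.17, Trimmomatic 0.33, Bowtie 1.1.2 and MACS2 2.1.0, and the human genome build hg19 (GRCh37). The role of each tool, the peak threshold and the control used for peak calling are not given in the sources used here. The authors deposited 1 peak list per immunoprecipitated library, so peaks were not pooled over replicates. Each deposited list has 4 columns, holding the chromosome, the start, the end and a peak name. The values used here are therefore positions in bp, and the lists carry no column of peak height, enrichment or significance. Read numbers are not given in the sources used here, so the sequencing depth of each library is unknown. Intervals printed beside shares of peaks are exact (Clopper-Pearson) 95% binomial intervals and cover counting error over peaks only.

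The smallest peak width and the smallest gap between neighbouring peaks differed from list to list. They were 221 and 222 bp in H3K27ac replicate 1 and 172 and 173 bp in H3K27ac replicate 2. In H3K4me1 replicates 1 and 2 they were 191 and 192 bp and 232 and 233 bp. Each list thus has its own minimum width and its own joining distance, which affects peak number and peak width and is examined among the alternatives.

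Comparisons used the autosomes and chromosome X, which left 54763, 64845, 118231 and 125320 peaks in H3K27ac replicates 1 and 2 and H3K4me1 replicates 1 and 2. No interval occurred more than once in a list. Positions are given in hg19 and counted from 1. The gene table at hand belongs to build GRCh38, and the chromosome 1 peaks of H3K27ac replicate 1 reach position 249238297, beyond the last gene of that table. Because the builds differ, no gene was assigned to any peak and regions are named by coordinate alone.

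Peaks of both libraries of a mark were merged where they overlapped, and a merged region holding at least 1 peak of each library was called a replicated region. An overlap of 1 bp or more counted as shared. Marks were compared by library with an exact two-sided permutation test of the difference of means, which cannot give p below 0.333 with 2 libraries per mark. Overlap of replicated regions of both marks was tested against 1000 placements of the H3K27ac regions at random positions of their own chromosomes, between the outermost peaks (one-sided permutation test, smallest possible p = 0.001). Benjamini-Hochberg adjustment was applied within each family of tests. H3K27ac regions within 12.5 kb of each other were joined into domains and ranked by the length of H3K27ac regions inside them. The planned order, by length times fold enrichment, needed values that the lists do not carry.

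These tests, the replicated regions, the 12.5 kb distance and the rule for naming regions were fixed before the data were examined. By that rule, in the absence of gene annotation of the same build, the text names the 10 top H3K27ac domains and the 5 widest replicated regions of each mark. The planned naming of the 5 peaks with the highest fold enrichment was dropped, because it needed fold enrichment too. Gene lists for prostate, epithelial and other cell types had also been fixed and were not used here, since each required start sites of the same build. Choices made after looking at the data are the use of region width in place of fold enrichment, the 5 width classes of nearly equal size, the position at 0.75 of the distance from the middle of a region to its end, the 5 Mb windows with at least 20 H3K27ac regions, the chromosomes, windows and 45 Mb boundary singled out in the text, the 20 kb limit for large domains, the 5 kb distance between marks, the weighting of width classes on chromosome 8, and the domains with H3K4me1 only. The 0.75 position and the windows were picked after a range of positions and window sizes had been viewed.

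Coverage along regions was the percentage of regions whose base at a given relative position lay in a region of the other mark, averaged over the left and right side. To compare it with chance, H3K4me1 coverage was rotated along each H3K27ac region by a random distance, 1000 times. Along chromosomes, neighbouring windows were compared by Spearman's rho over pairs of adjoining windows, against 1000 shuffles of windows within chromosomes. Intervals of rho across windows came from 1000 bootstrap resamples of windows, and neighbouring windows are not independent, so these intervals are too narrow. The variance between windows of the share of peaks found in both libraries was compared with binomial counting error, a check added after the result was seen. Intervals of differences of shares came from 10000 binomial draws. They treat regions as independent, which neighbouring regions are not, so they are too narrow as well.

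Alternatives covered an overlap of 50% of the shorter region, all chromosomes, the union of peaks, random moves of 50 to 500 kb, a 5 kb joining distance for domains, leaving out each replicate, a replicate block, a common minimum width and joining distance of 232 bp, and equal numbers of the widest peaks. Alternatives on significance thresholds and start sites were planned and not run. Overlap code was tested on simulated data before use. With 20%, 50% and 80% of 47128 H3K27ac regions placed on purpose on H3K4me1 regions, the expected overlaps were 26.3%, 53.9% and 81.6% and the recovered ones 26.0%, 53.9% and 81.5%. With none placed on purpose, 2 of 20 placement tests gave p of 0.05 or less, where 1 was expected. Weighting the width classes alike on both sides was tested on 2183 simulated regions, the number on chromosome 8. It gave a mean difference of 0.0961 points where 0 was expected and of 10.3 where 10 was expected. Over the 758 H3K27ac regions of chromosome 21, 0 overlap calls differed from a direct count. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.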

Results

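VCaP is an androgen-responsive human prostate cancer line. H3K4me1 is found at enhancers, active or not, and on the flanks of promoters, while H3K27ac marks active enhancers and active promoters. Peaks of both marks were mapped in cells for which the labels name no treatment, with 2 libraries for H3K27ac, 2 for H3K4me1 and 1 input. The design implies a comparison of where the marks lie in the same cells. Sequencing depth is unknown for all libraries, because the deposited lists hold positions and names of peaks only.

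H3K4me1 formed about 2 times as many peaks as H3K27ac. The H3K4me1 libraries held 121776 ± 5013 peaks (mean ± SD, n = 2) and the H3K27ac libraries 59804 ± 7129 (n = 2), a ratio of 2.04. Every pairing of an H3K4me1 with an H3K27ac library gave more H3K4me1 peaks, with ratios from 1.82 to 2.29. H3K27ac peaks had a mean of library medians of 762.5 bp (SD 197, n = 2) and H3K4me1 peaks one of 549 bp (SD 143, n = 2). In the lists as deposited these widths overlapped between marks, since the medians were 902 and 623 bp for H3K27ac replicates 1 and 2 and 448 and 650 bp for H3K4me1 replicates 1 and 2. With the common minimum width and joining distance of 232 bp, chosen after seeing the data, the medians no longer overlapped. They were 957 and 880 bp for H3K27ac and 521 and 650 bp for H3K4me1. The covered length was 73.2 and 67.8 Mb for H3K27ac and 72.4 and 112.1 Mb for H3K4me1, so that H3K4me1 replicate 1 lay between the H3K27ac libraries. The difference in peak number exceeded the spread between replicates, but the exact two-sided permutation test gave p = 0.333, the smallest value that 2 against 2 libraries allow. Width and covered length each gave an exact p of 0.667, and with the percentage of shared peaks (exact p = 1) the family held 4 tests, whose Benjamini-Hochberg adjusted values were between 0.889 and 1.

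**Figure D1:**
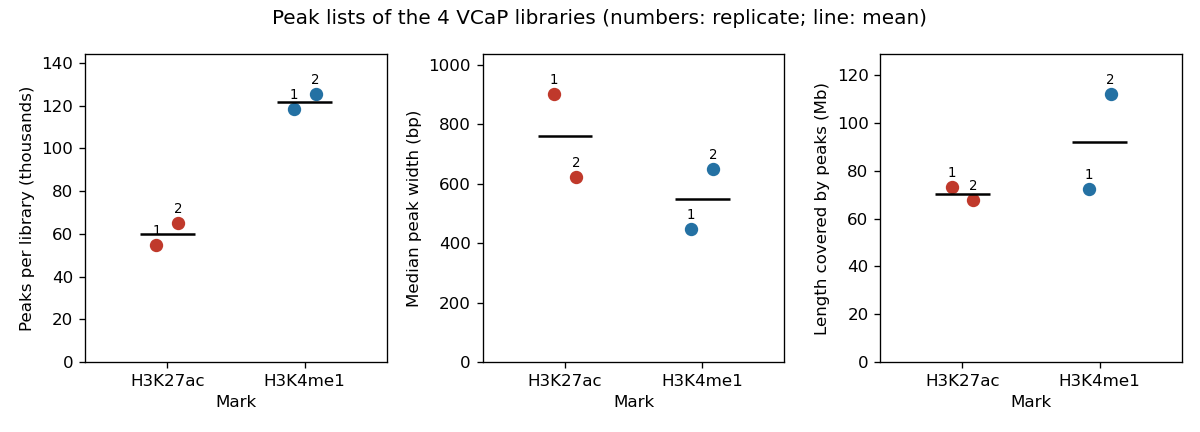
Number of peaks per library (axis in units of 1000), median peak width in bp and length covered by peaks in Mb for the 4 VCaP libraries, each point being 1 library with its replicate number and each line the mean of a mark. The H3K4me1 libraries lie at 118231 and 125320 peaks, above the H3K27ac libraries at 54763 and 64845, while widths and covered lengths of the marks overlap in these lists as deposited.

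H3K27ac peaks recurred between replicates more evenly than H3K4me1 peaks. Of H3K27ac peaks, 87.9% of replicate 1 (95% interval 87.6 to 88.2%) and 86.0% of replicate 2 (85.8 to 86.3%) overlapped a peak of the other library. Of H3K4me1 peaks, 88.3% of replicate 1 (88.2 to 88.5%) did so, against 68.7% of replicate 2 (68.5 to 69.0%). Peaks found in 1 library only were narrow, with medians of 311 and 240 bp for H3K27ac and 262 and 382 bp for H3K4me1, while shared peaks had medians of 1095 and 770 bp and of 493 and 869 bp. The bases covered in both libraries made up 76.9% of those covered in either for H3K27ac and 51.8% for H3K4me1. Across replicated regions, the width of the widest peak correlated between libraries with a Spearman's rho of 0.897 for H3K27ac and 0.669 for H3K4me1. These are correlations across regions, which are not independent replicates. Merging gave 47128 replicated H3K27ac regions (74.9 Mb, median 1217 bp) out of 62809 merged regions, and 84838 replicated H3K4me1 regions (99.8 Mb, median 944 bp) out of 137801.

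In the lists as deposited, most H3K27ac regions of VCaP cells also carried H3K4me1, and a little under 50% of H3K4me1 regions carried H3K27ac. Of 47128 H3K27ac regions, 34623 overlapped an H3K4me1 region, or 73.5% (73.1 to 73.9%). Of 84838 H3K4me1 regions, 39927 overlapped an H3K27ac region, or 47.1% (46.7 to 47.4%). The remaining 12505 H3K27ac regions and 44911 H3K4me1 regions overlapped no replicated region of the other mark. Some of them lay on a peak found in 1 library only. With all peaks of H3K4me1 replicate 2 counted, 80.9% of H3K27ac regions carried H3K4me1. With all peaks of H3K27ac replicate 2 counted, 50.7% of H3K4me1 regions carried H3K27ac. Random placement gave 7.61 ± 0.121% (SD over 1000 placements) for H3K27ac regions, with a maximum of 7.97%, and 4.59 ± 0.0764% for H3K4me1 regions, with a maximum of 4.81%. The observed shares were 9.66 and 10.3 times the random means, each with a one-sided permutation p of 0.001, the smallest that 1000 placements can give, and 0.001 after adjustment over both tests. The order of the shares turned round with only the widest peaks of each list, as many as the shortest list holds, where 50.1% of H3K27ac regions carried H3K4me1 and 61.6% of H3K4me1 regions carried H3K27ac. That setting changes the number and the width of peaks together. By length, H3K4me1 covered 51.7% of the replicated H3K27ac regions.

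The shares held in each pair of libraries as deposited. H3K27ac replicate 1 had 71.7% of its peaks on peaks of H3K4me1 replicate 1 and 79.8% on those of H3K4me1 replicate 2, and H3K27ac replicate 2 had 69.5 and 77.9%. H3K4me1 replicate 1 had 43.8% of its peaks on peaks of H3K27ac replicate 1 and 43.5% on those of replicate 2, and H3K4me1 replicate 2 had 39.6% on both.

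Regions that overlapped a replicated region of the other mark were wider than those that did not. The median width was 1319 bp for H3K27ac regions with H3K4me1 and 991 bp for those without, and 1194 and 789 bp for H3K4me1 regions with and without H3K27ac. By library, peaks on a region of the other mark were 1.32 and 1.11 times as wide as other peaks for H3K27ac replicates 1 and 2, and 1.73 and 1.89 times as wide for H3K4me1. Over 5 width classes, from narrowest to widest, the share of H3K27ac regions with H3K4me1 was 67.7, 69.1, 71.0, 74.7 and 84.8%. The share of H3K4me1 regions with H3K27ac was 28.4, 36.9, 42.8, 51.3 and 76.1%. A wide region meets another by chance more often than a narrow one, so part of these gradients follows from width alone.

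Across wide H3K27ac regions, H3K4me1 lay more often towards the ends than in the middle. In the widest 2 of 5 classes (18845 regions of 1539 to 30474 bp), H3K4me1 covered the middle of 37.2% of regions and the position at 0.75 of the way to the end in 56.6%, a ratio of 0.657. The dip was present with H3K4me1 replicate 1 alone (26.7% in the middle, 47.3% towards the ends) and with replicate 2 alone (36.5 and 58.2%). In the narrowest class (223 to 548 bp), which leaves little room for separate H3K4me1 peaks, the middle was covered in 66.2% and the outer position in 62.4% of regions. Among the wide H3K27ac regions, 3910 (20.7%) had H3K4me1 at 1 outer position and not in the middle, 2489 (13.2%) at both outer positions and not in the middle, 166 (0.881%) in the middle and at neither outer position, 1244 (6.6%) in the middle and at 1 outer position, 5592 (29.7%) at all 3 positions and 5444 (28.9%) at none.

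H3K27ac across wide H3K4me1 regions had the opposite shape. In the widest 2 of 5 classes of H3K4me1 regions (33904 regions), H3K27ac covered the middle of 48.1% and the outer position of 36.1%, a ratio of 1.33.

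**Figure D2:**
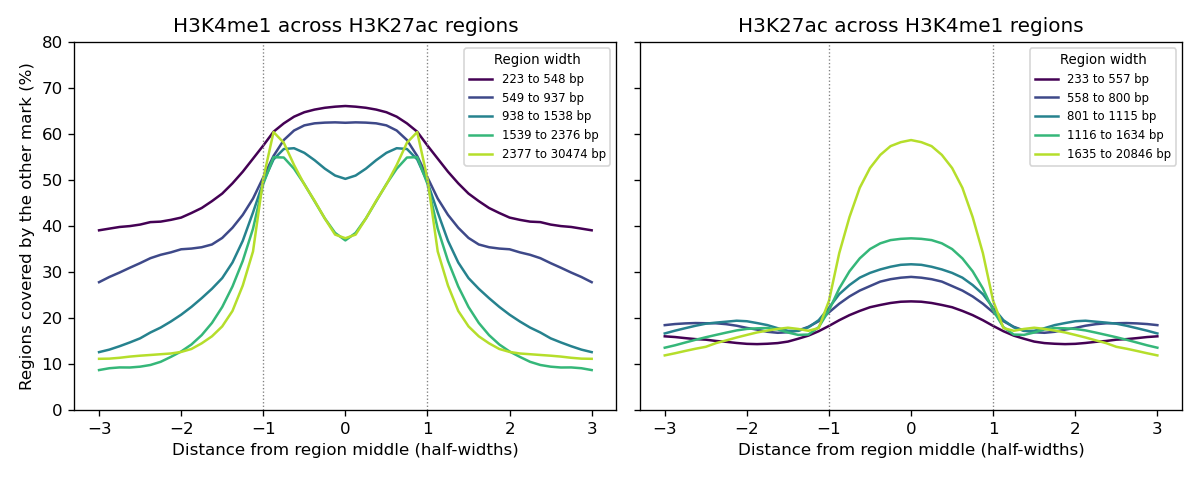
Percentage of regions covered by the other mark against distance from the region middle, in units of the distance from middle to end, with 1 line per width class and dotted lines at the ends of the region. H3K4me1 in the widest class of H3K27ac regions falls to 37.4% in the middle from 58.2% at 0.75, whereas H3K27ac in the widest class of H3K4me1 regions is highest in the middle, at 58.7%.

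Chromosome X and chromosome 16 had the lowest shares of H3K27ac regions with H3K4me1. The share was 40.8% on chromosome X (38.0 to 43.6%, 1192 regions) and 50.8% on chromosome 16 (48.1 to 53.5%, 1366 regions), against a median of 74.4% over 23 chromosomes. It was 62.5% on chromosome 19 and 66.0% on chromosome 6. The highest shares were 89.6% on chromosome 21 (87.2 to 91.7%, 758 regions) and 84.8% on chromosome 20 (82.8 to 86.7%, 1372 regions). Counted with H3K4me1 replicate 1 alone, chromosomes X, 16 and 21 gave 42.6, 52.7 and 89.3%, and with replicate 2 alone 50.6, 58.8 and 94.3%. The gap between chromosomes X and 21 was thus larger than that between libraries. The ratio of H3K4me1 to H3K27ac regions was 1.88 at the median chromosome, 1.12 on chromosome 16, 1.09 on chromosome 19 and 0.961 on chromosome X. On chromosome 19 the low ratio went with dense H3K27ac regions (33.1 per Mb against a chromosome median of 16.0). H3K4me1 regions were not sparse there (36.1 against 31.0 per Mb).

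**Figure D3:**
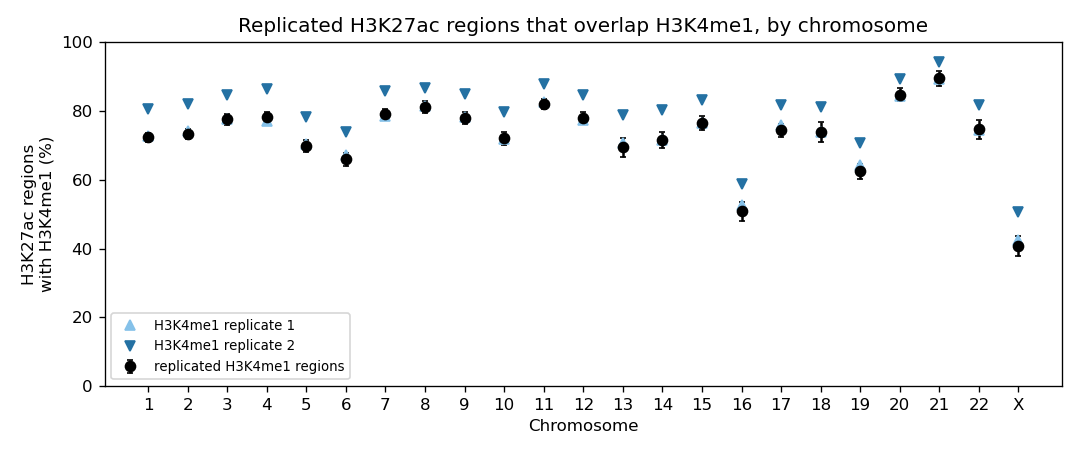
Percentage of replicated H3K27ac regions that overlap H3K4me1 on each chromosome, with circles for replicated H3K4me1 regions, bars for 95% binomial intervals and triangles for each H3K4me1 library alone. Chromosome X is lowest at 40.8% and chromosome 21 highest at 89.6%, with the same lowest and highest chromosome in each H3K4me1 library.

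The share also changed along chromosomes. On chromosome 8, 64.8% of the 664 H3K27ac regions in the first 45 Mb carried H3K4me1, against 88.4% of the 1519 regions in the rest, a difference of 23.7 percentage points (19.7 to 27.6). H3K4me1 replicates 1 and 2 alone gave differences of 21.95 (18.1 to 25.9) and 16.7 (13.2 to 20.3) points. H3K27ac peaks were about as dense on both sides, with 17.1 and 17.5 peaks per Mb in replicate 1 and 20.1 and 20.6 in replicate 2. H3K4me1 peaks were sparser in the first 45 Mb, with 31.7 against 49.7 per Mb in replicate 1 and 34.1 against 49.6 in replicate 2. On chromosome 6, the window from 15 to 20 Mb had H3K4me1 on 15.5% of 71 H3K27ac regions and the next window on 86.0% of 107. With H3K4me1 replicates 1 and 2 alone, the share in the window from 15 to 20 Mb was 28.2 and 23.9%, and in the next window 86.9 and 94.4%. On chromosome X, the window from 100000001 to 105000000 had a replicated H3K4me1 region on 0 of 35 H3K27ac regions. Since a count of 0 allows about 3, counting error alone would allow a share of up to 8.57%, an approximate bound and not an exact interval. Of the H3K4me1 replicate 2 peaks in that window, 0% were found in replicate 1. The count of 0 thus reflects a lack of replicated H3K4me1 in the window and is no trait of these 35 regions. H3K4me1 replicate 1 alone also gave 0 there, and replicate 2 alone 2.86%. These windows were picked after their values were seen.

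Over 547 windows of 5 Mb, the share ranged from 0 to 98.6% with a median of 73.9%. Adjoining windows resembled each other, with a Spearman's rho of 0.501 over 491 pairs, against a mean of 0.278 and a maximum of 0.410 in 1000 shuffles of windows within chromosomes (permutation p = 0.001, the smallest possible). The shares from the H3K4me1 libraries taken singly correlated across windows with a rho of 0.90.

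**Figure D4:**
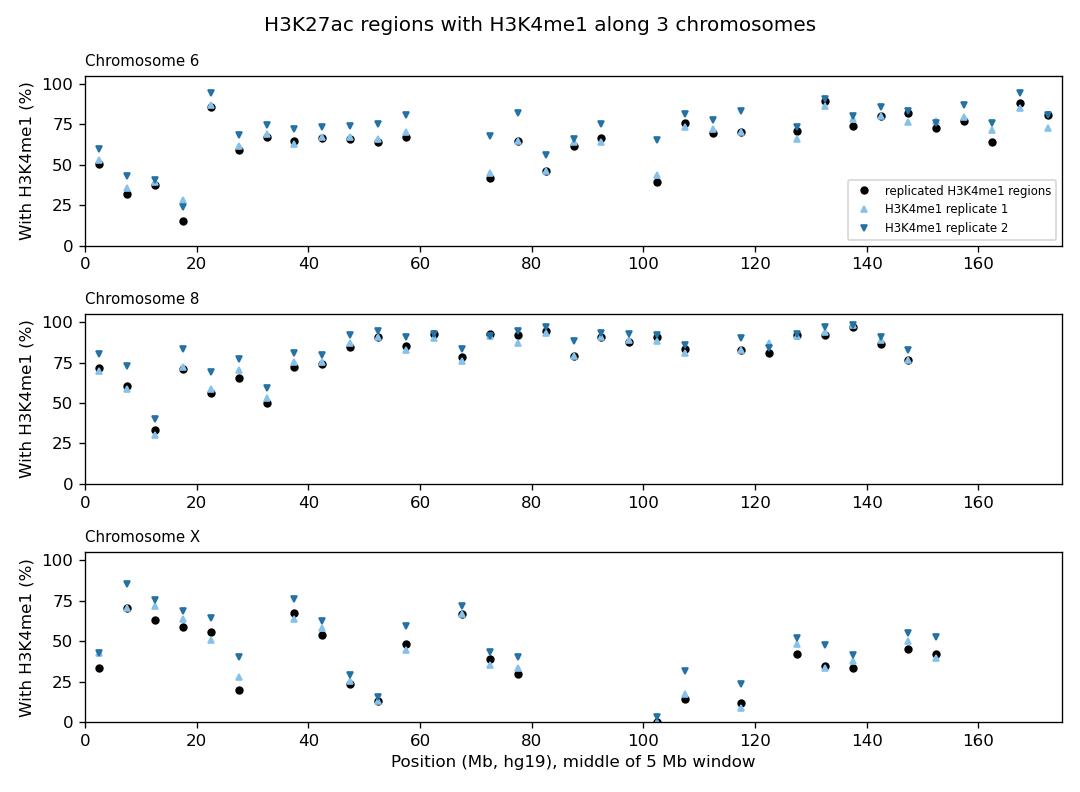
Percentage of H3K27ac regions with H3K4me1 in 5 Mb windows along chromosomes 6, 8 and X, plotted at the middle of each window in Mb (hg19), with circles for replicated H3K4me1 regions and triangles for each H3K4me1 library alone. The first 45 Mb of chromosome 8 lie below the rest (64.8 against 88.4% overall), and the window of chromosome X from 100000001 to 105000000 is at 0 with replicated regions and at 2.86% with H3K4me1 replicate 2 alone.

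Most H3K27ac domains were short, and a few were long. The domain with the most H3K27ac lay on chromosome 4 from 169920616 to 170124205, with 36 regions adding up to 89.4 kb. It was followed by a domain on chromosome 8 (134254215 to 134373928, 77.8 kb), one on chromosome 11 (113959250 to 114080689, 63.9 kb) and one on chromosome 7 (38254032 to 38360001, 62.6 kb). Joining gave 27436 domains with a median of 1.86 kb of H3K27ac, of which 16702 (60.9%) were a single region. The 122 domains with at least 20 kb of H3K27ac held 4.57% of its length, and all 122 overlapped H3K4me1 by at least 1 bp. Long domains meet a region by chance easily, and no random share was obtained for them. Rank 1 to 4 had similar H3K27ac lengths in each library, for example 89.1 and 77.4 kb on chromosome 4. In H3K27ac replicate 1 alone, rank 3 and 4 changed places, with 61.5 kb on chromosome 11 and 62.8 kb on chromosome 7. No test applies to this ranking, which rests on length because peak heights are not in the lists.

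H3K4me1 coverage differed widely among the top 10 domains. It made up 68.3% of the span of the chromosome 8 domain and 64.1% of that on chromosome 11 from 113959250, and 40.4% on chromosome 4. The domains on chromosome 11 from 65183226 to 65294201 (55.6 kb of H3K27ac), chromosome 3 from 131927983 to 132005973 (50.3 kb) and chromosome 9 from 140082182 to 140198170 (45.9 kb) had 26.98, 46.2 and 30.4%. The domain on chromosome 19 from 51338170 to 51395386 (40.5 kb) had 28.6% and the chromosome 7 domain from 38254032 had 32.7%. H3K4me1 was scarce in the chromosome 7 domain from 27187226 to 27250901, with 14.0% of the span against 85.1% for H3K27ac. It was lowest in the chromosome 22 domain from 46390938 to 46481797, with 2.74% against 51.3% for H3K27ac.

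**Figure D5:**
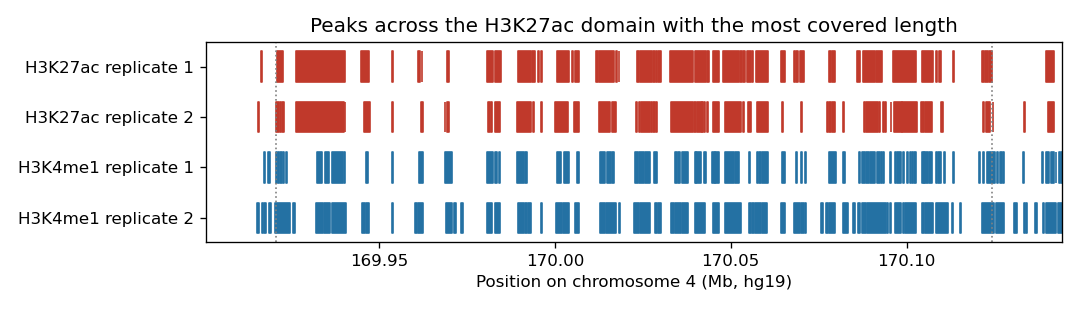
Peaks of the 4 libraries across the chromosome 4 domain from 169920616 to 170124205, by position in Mb (hg19), with 1 line of bars per library, each bar 1 peak drawn to scale, and dotted lines at the domain's ends. Both marks recur along the domain, where H3K27ac regions fill 43.9% and H3K4me1 regions 40.4% of the span.

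The widest H3K27ac region lay on chromosome 22 from 46447846 to 46478319 and carried no replicated H3K4me1 over its 30474 bp. The next, on chromosome 7 from 27222617 to 27248913 (26297 bp), had H3K4me1 over 11.2% of its length. Those on chromosome 19 (13122405 to 13146380), chromosome 20 (56263764 to 56287511) and chromosome 15 (99328171 to 99351410) had 46.4, 73.0 and 95.03%. The 5 widest H3K4me1 regions were all largely covered by H3K27ac. They lay on chromosome 20 (56255235 to 56276080, 20846 bp, 76.5% covered), chromosome 8 (134273117 to 134292752, 82.3%, and 134254603 to 134272828, 99.6%), chromosome 11 (113988747 to 114005416, 80.4%) and chromosome 15 (99332546 to 99346997, 100%). The chromosome 8 and chromosome 11 regions fall inside the H3K27ac domains of rank 2 and 3.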

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

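The comparisons leave out chromosome Y, a choice fixed before its counts were seen, and no test was run on it. All lists nevertheless held intervals there, 233 and 261 in H3K27ac replicates 1 and 2 and 320 and 385 in H3K4me1 replicates 1 and 2, each above the 3 that a count of 0 allows.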

How the results depend on the processing

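The common minimum width and joining distance, the equal numbers of widest peaks, and every alternative on region width or on coverage along regions were chosen after seeing the data; the others had been planned. Over 11 results and 71 alternatives, 65 kept their direction and, where there was a test, its call, or moved by no more than the spread between replicates; domain numbers stayed within 1.5 times. Counting every row is among the 71 and could not change a value, because no interval occurred more than once in a list. For the overlap shares only direction and call were compared, so a share could move widely and still count as kept. None reversed on its own, but equal numbers of widest peaks turned round which overlap share was the larger. The share of H3K27ac regions with H3K4me1 ranged from 50.1% with equal numbers of widest peaks to 82.4% with the union of peaks, and the share of H3K4me1 regions with H3K27ac from 37.0% without H3K4me1 replicate 1 to 61.6% with equal numbers of widest peaks, each above all random placements. Moves of 50 to 500 kb raised the random shares to 10.8 and 6.44%. Alternatives used 100 placements (smallest p 0.0099), or 20 for the 50% overlap (smallest p 0.0476). The mean share of H3K27ac peaks recurring between replicates fell to 85.3% with an overlap of 50% of the shorter peak, as a stricter criterion must lower it. Leaving out a replicate gave width ratios of 1.11 to 1.36 for H3K27ac and 1.55 to 1.89 for H3K4me1 regions with against without the other mark, and middle-to-end coverage ratios of 0.564 to 0.769; the cause was not tested. A joining distance of 5 kb gave 34277 domains, with 6 of the top 10 kept, and leaving out either H3K27ac replicate gave 29842 or 29292, with 10 of the top 10 kept. Same-numbered libraries of the marks did not deviate together (r = -0.0732 over 22951 windows of 100 kb). That value cannot show whether the numbers pair them, because depth is unknown and each list has its own minimum width and joining distance. A replicate block gave 74.8 and 41.7% for the overlap shares (74.6 and 41.6% with crossed numbers) and ratios of 2.05, 0.770 and 1.32 for peak number, width and covered length, and changed no call. Not run, for want of the columns or of start sites in hg19, were stricter thresholds and equal numbers by q-value, peak strength by fold enrichment or q-value, start-site proximity, gene lists and ranking by length times enrichment. Unknown depth limits every comparison of peak number and width between libraries.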

Other observations

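Among the tests in this part, the rotation of H3K4me1 coverage along H3K27ac regions, the test of H3K4me1 detection by window and the weighting of width classes on chromosome 8 were chosen only after the results they bear on had been seen, as were the 5 kb distance and the description of domains with H3K4me1 only.

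H3K4me1 regions without a replicated H3K27ac region on them lay near H3K27ac more often than random positions did. The 44911 such regions had a median distance of 15.3 kb to the nearest H3K27ac region, and 28.0% lay within 5 kb, against a mean of 15.9% and a maximum of 16.3% over 100 random placements. The 12505 H3K27ac regions without a replicated H3K4me1 region on them lay a median of 7.96 kb from the nearest H3K4me1 region, with 41.1% within 5 kb. No random share was obtained for them, so the 41.1% cannot be set against chance or against the 28.0%. Entire H3K4me1 domains also stood apart from H3K27ac. Of 38224 domains made by joining H3K4me1 regions over the same distance as H3K27ac regions, 15188 (39.7%) held no H3K27ac peak of either library. The domain of this kind with the most H3K4me1 lay on chromosome 3 from 31773955 to 31814200, with 9 regions adding up to 14.3 kb. The next were on chromosome 21 (39760203 to 39781291, 12.8 kb), chromosome 19 (43843231 to 43906455, 12.4 kb), chromosome 2 (67504217 to 67564246, 9.89 kb) and chromosome 3 (171852745 to 171875458, 9.64 kb).

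Replicates of a mark differed in median peak width by 1.45 times, for H3K27ac and for H3K4me1 alike. With the largest minimum width and joining distance of the 4 lists applied to all, the H3K27ac ratio fell to 1.09, with medians of 957 and 880 bp, so that unequal settings may account for most of that gap. The H3K4me1 ratio fell to 1.25, with medians of 521 and 650 bp, above the 1.2 set beforehand as arguing against unequal settings as the whole cause. Unequal depth stays open for the remainder, and no biological explanation was tested.

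The dip of H3K4me1 in the middle of wide H3K27ac regions did not arise from joining the peaks of both libraries. In the 4 pairs of lists as deposited, the highest ratio of middle to outer coverage was 0.744. The observed 0.657 also lay below the lowest of 1000 rotations, 0.976, which shows only that it exceeds counting noise, since rotation makes all positions alike. One hypothesis is that some wide regions may be active promoters, where H3K4me1 is known to flank the start site and other methylation states of lysine 4 to occupy the centre. Start sites of the same build were not used here, so no biological explanation was tested, and splitting of broad H3K4me1 signal by the peak caller also stays open.

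Changes of the H3K4me1 share along chromosomes might come from windows in which any peak is easier to detect, as differences in DNA copy number would make them. The test set beforehand gave a rho of 0.0695 (-0.023 to 0.165) between the share and the share of H3K27ac replicate 2 peaks found in replicate 1. It lay below the bound set beforehand as arguing against this cause. A check added after the result was seen showed that the test could not decide. Only 4.80% of the variance between windows of the share found in replicate 1 exceeded counting error. Some values go with easier detection of any peak. The share rose with the median width of H3K27ac regions (rho 0.280, 0.205 to 0.360). Peaks were narrower in the first 45 Mb of chromosome 8 than in the rest. This held in H3K27ac replicates 1 (medians 807 and 940 bp) and 2 (615 and 643 bp). It also held in H3K4me1 replicates 1 (404 and 510 bp) and 2 (576 and 787 bp). Chromosome X, with the lowest share, was sparse in both marks. Its H3K27ac region density was 7.68 per Mb against a chromosome median of 16.0, and its H3K4me1 density 7.38 against 31.0. Other values go against easier detection that acts alike on both marks. On chromosome 8, H3K27ac peak densities were near-equal on both sides (17.1 and 17.5 per Mb, 20.1 and 20.6 per Mb). H3K4me1 densities were lower in its first 45 Mb (31.7 and 49.7 per Mb, 34.1 and 49.6 per Mb). Chromosome 16 had an H3K27ac region density of 15.1 per Mb against the median of 16.0, beside 17.0 against 31.0 for H3K4me1. These densities cannot decide where detection affects H3K4me1 peaks more than H3K27ac peaks. For the share of H3K4me1 replicate 2 peaks found in replicate 1, 78.4% of the variance between windows exceeded counting error. The width of H3K27ac regions did not make up the chromosome 8 difference. It was 22.6 points (18.7 to 26.5) with width classes of H3K27ac regions weighted alike, above the under-10 of such a cause. It was 23.2 (17.6 to 28.8) in narrower and 22.8 (17.3 to 28.4) in wider H3K27ac regions. The interval for narrower regions did not exclude 20 as required beforehand. These intervals treat neighbouring regions as independent and are too narrow. The width of H3K4me1 peaks was not weighted, so its part stays open, as does a part of width in other windows. Weaker detection of H3K4me1 alone is a candidate explanation, since the share counted with H3K4me1 replicate 2 rose with the share of its peaks found in replicate 1 (rho 0.423, 0.348 to 0.498), but a regional loss of H3K4me1 would look alike.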
